A study of Mus musculus with 36 samples.

How the data were processed

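Gene expression was measured by RNA sequencing in 36 libraries of mouse lymphocytes from a study of alopecia areata, an autoimmune loss of hair. Per the labels' protocols, RNA was extracted with Trizol, 500 ng of total RNA entered each library, and the Lexogen QuantSeq kit was used, which reads the 3' ends of polyadenylated transcripts. The labels name lymph node or skin as tissue and 3 kinds of mice: spontaneous alopecia areata (SP), alopecia areata by adoptive transfer (AT) and naive mice. They also name 3 cell subsets as Tn, Tvm and CD44shi without spelling these out. From the study's title and field, Tn is read here as naive CD8+ T cells, Tvm as virtual memory T cells, which carry memory markers without having met foreign antigen, and CD44shi as cells with very high CD44, an adhesion receptor of activated T cells. The sort gates are not given in the sources used here.

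Each library came with a deposited table of whole-number counts per gene symbol, read as raw counts because the values were whole and the library totals differed. Bowtie2 and bedtools on the mm10 build were used, per the submitters' processing notes, with their versions, the gene annotation and the strand setting not given in the sources used here. Reads from near-identical copies and from overlapping or antisense genes therefore cannot be told apart. The counts of ribosomal protein genes, Ly6c2, Hspa1a, Klrc1, Hba-a1, the H2 class II genes, Airn and Tmevpg1 are uncertain in this sense. The tables held 23282 gene symbols. Entries that repeated a symbol, 44 for 35 symbols, were kept as separate entries and not summed. In 4 libraries (SP LN CD44shi replicate 2 and AT skin CD44shi replicates 1 to 3) the column header named another library number than the name of the file, and the sample record was followed.

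The 45S ribosomal RNA precursor Rn45s took 9.18% to 65.0% of a library (mean 43.0%). Library totals ran from 2028265 to 11943127 counts, and from 1842010 to 7315270 without Rn45s. Genes with a count numbered 4900 to 12353 per library (mean 9185), and on average 11.2% of the detected genes had fewer than 10 counts, so that a gene was mostly either absent or well counted. The kit's reads carry no molecular identifier in these tables, so reads are not independent molecules, and intervals and floors given here cover counting error only. The file names follow 3 styles, called file-name sets here, with 5, 17 and 14 libraries. They differed in the mean number of detected genes (11405, 9516 and 7990) and in edgeR's biological coefficient of variation (0.473, 1.24 and 1.53), and the set was used as a possible batch, although no label names one. The set and the group are partly confounded: naive mice occur in set 2 alone and SP mice only in sets 1 and 3.

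Groups followed the sample titles. With the number of libraries in each, they were naive-mouse LN Tn (3), naive-mouse LN Tvm (4), SP LN Tn (2), SP LN Tvm (5), SP LN CD44shi (4), SP skin CD44shi (1), AT LN Tn (2), AT LN Tvm (6), AT LN CD44shi (5) and AT skin CD44shi (4). The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, part of which may be technical. Among 58 pairs of libraries of 1 group none held identical values, and the lowest chi-square per degree of freedom between such a pair was 21.3, far above sampling noise.

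The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, fitted to 35 libraries of all groups with terms for group and file-name set, after TMM scaling. The single SP skin library was left out of the fit and is described by its values. Genes had to reach 1.21 CPM, or 10 counts at the median library, in at least 3 libraries, which kept 12690 genes. P-values were adjusted over these genes by the Benjamini-Hochberg method, and "rose" or "fell" stands for an adjusted p under 0.05. Levels are mean CPM on the TMM scale ± SD over the libraries of a group. In the test, all groups shared 1 estimate of a gene's spread, so p-values do not follow from the SDs printed beside them. A gene that did not pass is not shown to be at equal levels. Fold changes are the fitted log2 values ± standard error, which include the set term. A gene at 0 in a whole group gets a lower bound on its fold, computed against a floor of 3 counts over that group, and a gene with 1 to 3 counts in a group gets the 95% counting interval of the ratio.

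There were 11 comparisons, numbered in this order: C1, AT CD44shi against AT Tvm; C2, SP CD44shi against SP Tvm; C3, AT skin against AT lymph node CD44shi; C4, AT Tvm against naive-mouse Tvm; C5, Tvm against Tn in naive mice; C6, SP Tvm against naive-mouse Tvm; C7, Tvm against Tn in AT mice; C8, Tvm against Tn in SP mice; C9, the C1 change minus the C2 change; C10, AT Tn against naive-mouse Tn; C11, SP Tn against naive-mouse Tn. All are within lymph node except C3. In C6, C10 and C11 no file-name set holds both groups, and those results rest on the set term being additive.

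The groups, comparisons, main model, alternatives and gene lists, and the rule for naming genes, were fixed before the data were examined. The 26 lists held 492 genes, of which 485 were found. They covered cytotoxic effectors, NK receptors, naive and quiescence genes, virtual memory markers, tissue residency, tissue egress, inhibitory and costimulatory receptors, cytokines and chemokines, receptors of IL-12, IL-15 and IL-18 signalling, chemokine receptors, effector and memory transcription factors, interferon response, proliferation, glycolysis, oxidative phosphorylation, T cell receptor-induced genes, stress and immediate-early genes, adhesion molecules, ribosomal proteins, and markers of keratinocytes, fibroblasts and endothelium, B cells, myeloid and dendritic cells, CD4+ and regulatory T cells, gamma-delta and innate T cells, and red cells and platelets. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, and with fry. Camera compares the test statistics of a list with those of the other genes, so that its direction can differ from that of the list's median fold.

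Genes were named by this rule. For C1 to C5 they were the 8 with the largest and the 8 with the most negative fold among those with an adjusted p under 0.05, a mean CPM of both groups together of at least 5 and the same sign in every file-name set holding both groups. Predicted models, T cell receptor and immunoglobulin segments, histone, haemoglobin and microRNA genes were left out of this part. Added to them were the 2 to 4 members with the smallest adjusted p in each list described and 20 focus genes whatever their result. For C6 to C11 the 4 largest each way were taken. Of the genes this rule names, 3 were tested like all others but are not reported here. Gene positions are from GENCODE vM21, which annotates the same build.

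Alternatives fixed beforehand were DESeq2's size factors in edgeR, no low-count filter, the DESeq2 1.42.0 Wald test, no set term, the replicate number as a block, only the groups compared, each file-name set alone, the animal named in some file names as a block, and leaving out each library in turn. Chosen after seeing the data were leaving out Rn45s, leaving out set 3, limma-voom with library quality weights, an animal block from the column headers, and leaving out the 2 AT skin libraries with the most keratinocyte signal. The labels do not state whether replicate numbers pair the samples. The main test did not pair them, and the replicate block is described in the closing section. The animal blocks were fitted to SP CD44shi and SP Tvm only, with the animal in place of the set term.

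The scripts were tested on simulated counts with 200 changed genes, drawn from the means and library sizes of the real libraries and edgeR's fitted dispersions. Apart from the changed genes, all groups and file-name sets shared 1 mean profile. For C1, edgeR found 3% of genes changed 2-fold, 10.4% of those changed 4-fold and 56.1% of those changed 16-fold among 12413 genes, with 1 false call. For C2, C3, C4 and C5 it found 28.8%, 37.9%, 40.9% and 24.2% of genes changed 16-fold, with 0, 2, 0 and 0 false calls. For C6 to C11 it found 16.7%, 19.7%, 22.7%, 30.3%, 9.1% and 6.1% of them, with 1 or 2 false calls, or 0 in C8. At this depth and spread most changes of 4-fold, and outside C1 most changes of 16-fold, were therefore not detected by edgeR in the simulated tables. DESeq2 made 138 to 449 false calls on the same simulated tables, and its counts on the real data are given only as alternatives. These tables used edgeR's own dispersions and held no set effect. They cannot show that edgeR keeps its error rate on the real data, or how many of DESeq2's calls there are false.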

Results

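The data comprised 36 QuantSeq libraries of lymphocyte subsets from lymph node (LN) and skin of mice with spontaneous alopecia areata (SP), of mice with the disease after adoptive transfer (AT) and of naive mice. The deposited counts of a library summed to between 2028265 and 11943127. The study concerned a cytotoxic CD8+ T cell population thought to arise from virtual memory cells. The comparisons addressed how CD44shi cells differed from Tvm cells in both models, how CD44shi cells differed between skin and LN, and how Tvm cells differed from naive cells and between mice. Cd44 itself served as a check of the labels. It was at 0 to 1.22 CPM in every Tn library, at 43.6 to 142 CPM in every Tvm library and at 278 CPM or more in every CD44shi library of the AT model. In SP LN CD44shi it ranged from 42.5 to 760 CPM, and the lowest value, in replicate 3, lay under that of every Tvm library.

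In AT mice, CD44shi cells of the LN carried more transcript of the granzymes Gzmb and Gzma and of tissue-residency genes than Tvm cells, and less of genes of naive cells. Gzmb, which encodes the granule protease granzyme B (chromosome 14, 56258838 to 56262260), stood at 222 ± 112 CPM (SD, n = 5) against 1.78 ± 2.54 CPM (n = 6), a log2 fold change of 7.32 ± 1.07. Gzma, for granzyme A (chromosome 13, 113093825 to 113100981), rose from 5.71 ± 5.38 to 255 ± 126 CPM. Itgae, which encodes the integrin CD103 that binds E-cadherin on epithelia (chromosome 11, 73090583 to 73147446), rose from 9.13 ± 8.95 to 158 ± 106 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 3.13e-05 for Gzmb, 5e-05 for Gzma and 0.00275 for Itgae.

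Among lists, 5 of the 16 measured tissue-residency genes rose and none fell, the same 5 when adjusted over the list alone (camera adjusted p = 2.26e-11). They included Rgs2 and Rgs1, regulators of G protein signalling, at log2 folds of 2.19 ± 0.20 and 2.05 ± 0.33, and the chemokine receptor Cxcr6 at 2.99 ± 0.45. Of 17 cytokine and chemokine genes 2 rose (6 adjusted over the list alone; camera adjusted p = 3.05e-10): Csf1, the growth factor of macrophages, from 2.54 ± 3.67 to 203 ± 97 CPM, and Ifng, for interferon gamma, at 2.67 ± 0.74 (adjusted p = 0.0483). Cytotoxic effectors had 2 of 15 rising, Gzmb and Gzma, while the list's median fold was -0.21, its mean 0.74 and its camera test pointed up (adjusted p = 0.00039). Prf1, for the pore protein perforin, was at 16.9 ± 22.5 against 19.1 ± 11.7 CPM and passed no test. Of 38 proliferation genes 3 rose (10 adjusted over the list alone; camera adjusted p = 7.38e-19), Top2a, Mki67 and Hmgb2, which act in dividing cells. Mki67 was at 183 ± 60 against 10.8 ± 4.5 CPM. Of 22 effector and memory transcription factors 2 rose (7 adjusted over the list alone; camera adjusted p = 2.01e-05): Id2, an inhibitor of E proteins, at 3.69 ± 0.32, and Rora at 3.52 ± 0.67. Of 15 chemokine receptors 2 rose (7 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.000465), Cxcr6 and Cx3cr1, the latter at 7.37 ± 1.10.

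Of 20 naive and quiescence genes 5 fell and none rose (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.15e-05). Satb1, a chromatin organiser of T cells, fell by 1.98 ± 0.37 on the log2 scale, Foxo1 by 1.82 ± 0.46 and Actn1 by 2.57 ± 0.69. Of 40 ribosomal protein genes 27 fell (35 adjusted over the list alone; camera adjusted p = 6.33e-09), and this call was lost at an adjusted p = 0.0904 with an estimated correlation. Their summed level was 25957 ± 6294 against 48396 ± 1936 CPM, and Rpl13 fell by 1.18 ± 0.17 on the log2 scale. CD44shi libraries also detected fewer genes, 7593 ± 1147 against 10416 ± 880, with no overlap in file-name set 2 or 3. Inhibitory and costimulatory receptors rose in 2 of 15 (5 adjusted over the list alone; camera adjusted p = 1.24e-05), Icos at 1.98 ± 0.37 and Havcr2, the inhibitory receptor TIM-3, with 771 counts against 2, a ratio of 126 to 3775 by its 95% counting interval. Adhesion genes had 3 of 17 rising and 1 falling (the same adjusted over the list alone; camera adjusted p = 7.29e-06). Stress and immediate-early genes had 2 of 20 rising, Fos and Fosb (5 adjusted over the list alone; camera adjusted p = 1.36e-05).

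Markers of other cells moved as well. Of 16 myeloid and dendritic cell markers 3 rose (3 adjusted over the list alone; camera adjusted p = 5.05e-07), all of them genes of MHC class II: H2-Aa at 68.3 ± 98.7 against 0.393 ± 0.614 CPM, H2-Eb1 and Cd74. CD44shi replicate 3 held the highest value of H2-Aa, 240.8 CPM; without it the calls of H2-Eb1 and Cd74 were lost (adjusted p = 0.0865 and 0.156) and that of H2-Aa held (adjusted p = 0.015). The summed markers stood at 453 ± 285 against 198 ± 48 CPM. Of 8 markers of CD4+ and regulatory T cells 1 rose, Cd40lg, the ligand of CD40 (3 adjusted over the list alone; camera adjusted p = 0.0145), at 55.4 ± 54.0 against 0.291 ± 0.655 CPM. Every list named so far for this comparison kept its camera call with an estimated correlation except that of the ribosomal proteins. By fry, the calls of cytotoxic effectors, chemokine receptors and myeloid markers were lost, each at an adjusted p = 0.0776. Fry also lost inhibitory and costimulatory receptors (adjusted p = 0.0719), stress genes (0.132) and markers of CD4+ and regulatory T cells (0.302). The ribosomal proteins passed by fry (adjusted p = 4.53e-06). Keratinocyte markers (camera adjusted p = 0.0131) had no called member, and this call was lost at an adjusted p = 0.316 with an estimated correlation. T cell receptor-induced genes had 1 of 20 rising, Il2ra, and 1 falling, Spry2, a damper of receptor signalling (camera adjusted p = 0.0114; adjusted p = 0.0939 with an estimated correlation). No member of the interferon response or oxidative phosphorylation list passed (camera adjusted p = 0.0145 and 0.00935, both an adjusted p = 0.262 with an estimated correlation). The remaining lists passed no camera test, at adjusted p = 0.118 for NK receptors, 0.178 for virtual memory markers, 0.643 for tissue egress, 0.332 for cytokine receptors and 0.1 for glycolysis. The adjusted p was 0.183 for fibroblast and endothelial markers, 0.118 for B cell markers, 0.221 for gamma-delta and innate markers and 0.118 for red cell and platelet markers. Cd226, an activating receptor of the NK list, rose at 3.74 ± 1.01 (adjusted p = 0.0416). The egress list had 2 members rising, Itgb1 and Cx3cr1, and 2 falling, among them Klf3, and its median of -1.48 went against the direction of its camera test.

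The largest rises among named genes were in Gstm5, a glutathione transferase, at least 628-fold from 0 counts in Tvm, and in Arnt2, Tmem176b, H2-Aa, Adgrg1, H2-Eb1, Havcr2 and Hlf, at log2 folds of 7.62 to 8.49. The largest falls were in Dhx33, Atp10d, Uckl1, Gyg, Grasp, Aga, Inafm2 and Per2, each at 0 in all 5 CD44shi libraries and at least 204-fold to 289.5-fold lower. These bounds cover counting error only and not the lower number of genes detected in CD44shi libraries. Jak1, a kinase of cytokine receptors, fell by 0.92 ± 0.19, Bcl2, a survival factor, by 1.32 ± 0.32 and Klf3 by 4.13 ± 1.14 on the log2 scale. Itgb1 rose at 1.79 ± 0.41, Il2ra at 5.95 ± 1.44, Cd8a, for the CD8 alpha chain, at 0.86 ± 0.24 (adjusted p = 0.0477) and Cd44 at 2.21 ± 0.39. Of the other focus genes, none passed. Eomes, a transcription factor of memory CD8+ T cells (chromosome 9, 118478212 to 118486132), was at 79.7 ± 46.3 against 415 ± 247 CPM (adjusted p = 0.087) and Klrk1, for the activating receptor NKG2D, at 140 ± 43 against 32.6 ± 16.8 CPM (adjusted p = 0.159). Ly6c2 was at 323 ± 105 against 1054 ± 208 CPM, Cxcr3 at 164 ± 65 against 57.2 ± 36.3 CPM and Pdcd1 at 5.51 ± 8.71 against 0.320 ± 0.505 CPM. Il2rb was at 497 ± 115 against 749 ± 211 CPM and Tbx21 at 123.5 ± 52.4 against 77.9 ± 29.8 CPM. Fasl was at 43.5 ± 19.0 against 31.1 ± 11.4, Il18r1 at 410.5 ± 344.3 against 232 ± 130 and Itga4 at 9.30 ± 9.01 against 7.03 ± 9.27 CPM. Il12rb2 had no counts in CD44shi and 4.62 ± 3.43 CPM in Tvm (adjusted p = 0.135).

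In all, edgeR called 208 of 12690 genes in this comparison, 64 higher and 144 lower, and 40 of them were at 0 in 1 of the groups. The median log2 fold of all tested genes was -0.344. DESeq2's size factors moved it by 0.143 and split the calls as 74 higher and 98 lower, with 18 ribosomal protein genes called lower. The count fell to 110 without CD44shi replicate 4, 130 without CD44shi replicate 1 and 133 without Tvm replicate 6, and was 204 in set 2 alone and 12 in set 3 alone. Leaving out 1 library at a time, 27 of the 51 named calls held throughout; those of Ifng, Cd226, Cd8a, Spry2, Cd74 and Hmgb2 were lost most often and those of Havcr2, Hlf, Tmem176b, Arnt2, Klf3, Actn1, Aga and Per2 in at least 4 of the fits. Under at least 1 of the other alternatives 47 of the 51 were lost.

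**Figure D1:**
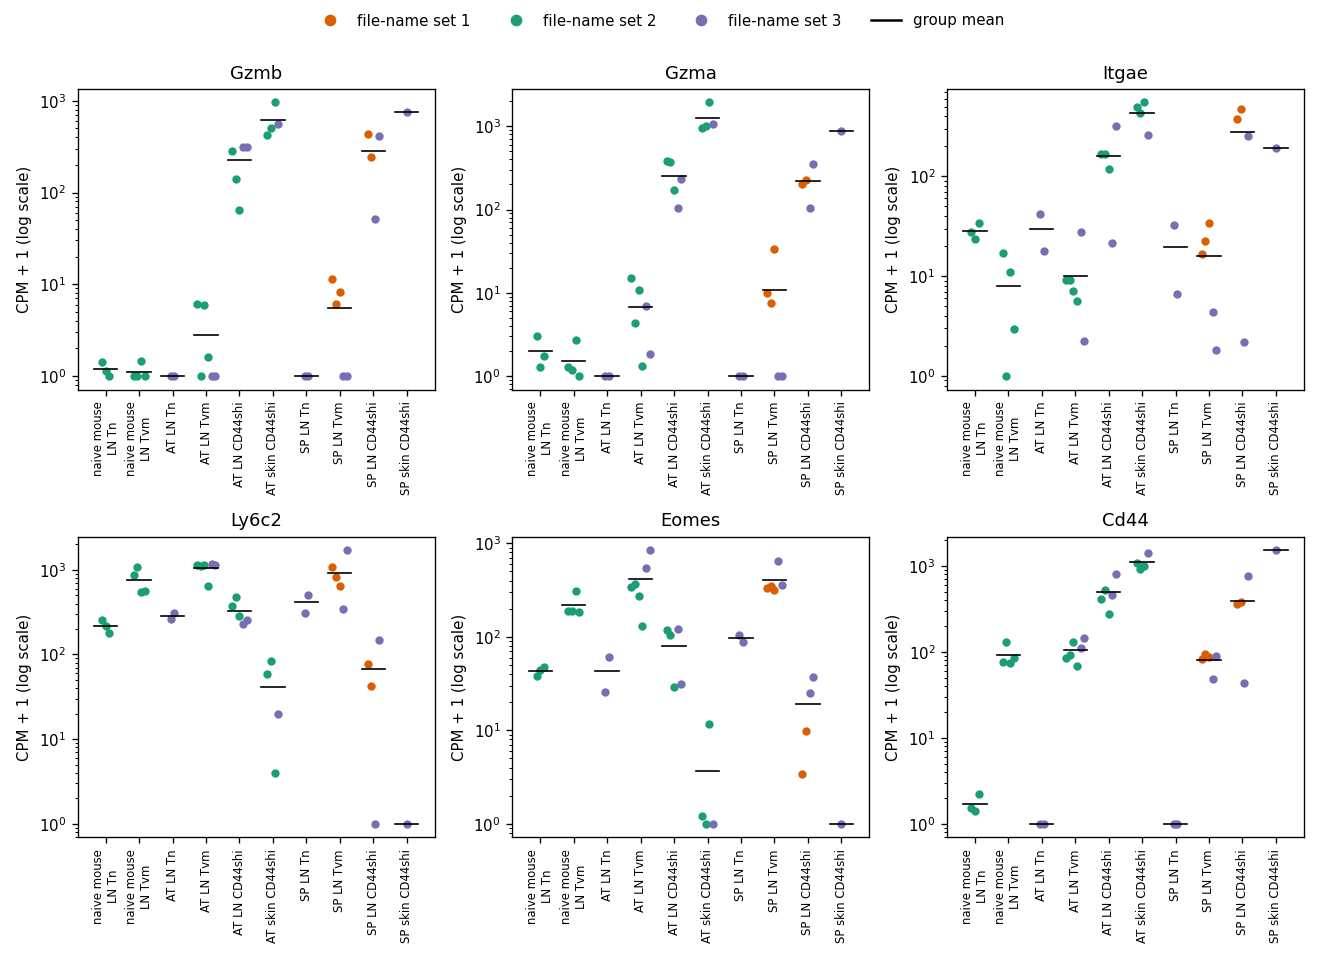
Level of Gzmb, Gzma, Itgae, Ly6c2, Eomes and Cd44 in each library as CPM + 1 on a log scale (y axis) by group (x axis), with points coloured by file-name set and a bar at the group mean. Gzmb had a mean of 222 CPM in AT LN CD44shi, 286 CPM in SP LN CD44shi and 1.78 and 4.56 CPM in the corresponding Tvm groups.

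In SP mice, CD44shi cells differed from Tvm cells in many of the same genes. Gzmb was at 286 ± 180 CPM (n = 4) against 4.56 ± 4.60 CPM (n = 5), Gzma at 219 ± 101 against 9.67 ± 13.54 CPM and Itgae at 274 ± 202 against 14.8 ± 13.3 CPM, and all rose. Pdcd1, for the inhibitory receptor PD-1, rose from 1 count over the 5 Tvm libraries to 50.2 ± 60.7 CPM, a ratio of 321 to 70850 by its 95% counting interval. Eomes fell from 394 ± 117 to 17.9 ± 15.3 CPM. The adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.000104 for Gzmb, 0.000384 for Gzma, 0.00114 for Itgae, 0.00463 for Pdcd1 and 0.000547 for Eomes.

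Tissue-residency genes rose in 5 of 16 (5 adjusted over the list alone; camera adjusted p = 3.68e-07), with Rgs2 at a log2 fold of 2.36 ± 0.23, Rgs1 at 2.19 ± 0.37 and Cxcr6 at 2.90 ± 0.50. Cytokines and chemokines rose in 3 of 17 (7 adjusted over the list alone; camera adjusted p = 2.48e-13): Csf1 at 7.22 ± 1.38, Ifng at 3.48 ± 0.84 and the chemokine Ccl4 at 2.40 ± 0.58. Naive and quiescence genes fell in 10 of 20 and rose in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 9.64e-13), among them Satb1 at -2.88 ± 0.44, Ccr7, the receptor that guides T cells into LN, at -4.91 ± 0.81, S1pr1, which guides them out, at -5.25 ± 1.02, and Lef1 at -5.88 ± 1.19. Ribosomal protein genes fell in 37 of 40 (40 adjusted over the list alone; camera adjusted p = 3.51e-32), with a summed level of 18434 ± 2688 against 55628 ± 7694 CPM; Rpl13 was at -1.85 ± 0.19 and Rps18 at -2.62 ± 0.30. Adhesion genes rose in 3 of 17 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 1.15e-05), with Itgal, part of the integrin LFA-1, at 1.72 ± 0.34. These calls and that of the transcription factors (2 of 22 rose and 2 fell, the same adjusted over the list alone, camera adjusted p = 0.0142), with Id2 at 4.04 ± 0.37, Rora at 4.18 ± 0.73, Eomes and Lef1, held with an estimated correlation. By fry the call of the transcription factors was lost (adjusted p = 0.178).

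Other camera calls were lost with an estimated correlation. Lost were those of cytotoxic effectors (2 of 15 rose; camera adjusted p = 0.0142, adjusted p = 0.115 with an estimated correlation), inhibitory and costimulatory receptors (1 of 15, Pdcd1; 0.012, and an adjusted p = 0.102 with an estimated correlation) and stress genes (3 of 20, Fos, Klf6 and Jund; 0.00493, and an adjusted p = 0.131 with an estimated correlation). The calls of proliferation genes (0 of 38; 0.006, and an adjusted p = 0.243 with an estimated correlation) and myeloid markers (0 of 16; 0.000178, and an adjusted p = 0.11 with an estimated correlation) were lost too. So were those of oxidative phosphorylation, which lay lower (0 of 38; 0.0144, and an adjusted p = 0.32 with an estimated correlation), and of markers of CD4+ and regulatory T cells (0 of 8; 0.0295, and an adjusted p = 0.0694 with an estimated correlation). The latter summed to 366 ± 47 against 146 ± 50 CPM. Mki67 was at 45.8 ± 12.7 against 13.6 ± 8.7 CPM (adjusted p = 0.641). Among tissue-egress genes 5 of 10 fell and 1 rose, with a camera adjusted p = 0.107.

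The largest rises were in Cmklr1, a chemoattractant receptor, at least 495-fold from 0 counts, and in Pdcd1, Anxa1, Sema6d, Gstm5, Cish, Gzmb and Cx3cr1, at log2 folds of 7.41 to 9.22. The largest falls were in Tmevpg1, at least 378-fold, Airn, at least 106-fold, Treml2, Plac8, Txk, a T cell kinase, Klf3, Lef1 and Pde2a. Cd8a rose at 1.55 ± 0.27, Cd44 at 2.30 ± 0.43, Klrc1, for the receptor NKG2A, at 2.60 ± 0.62 and Egr1 at 1.68 ± 0.45; Bcl2 fell by 2.38 ± 0.37 and Ly6c2, a surface marker of memory CD8+ T cells, by 3.82 ± 0.74 on the log2 scale. Klrk1 was at 216 ± 124 against 47.1 ± 41.5 CPM and did not pass (adjusted p = 0.117). Neither did Prf1 at 27.0 ± 29.8 against 10.3 ± 6.8 CPM or Fasl at 45.7 ± 24.3 against 24.9 ± 20.6 CPM. Nor did Tbx21 at 105 ± 35 against 61.8 ± 40.8 CPM or Il2rb at 422 ± 121 against 680 ± 358 CPM. Il18r1 was at 533 ± 174 against 275 ± 98 CPM and Cxcr3 at 200.02 ± 40.68 against 120 ± 62 CPM, and neither passed. Itga4 and Il12rb2 were at or under 4.29 CPM in both groups.

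In all, 168 of 12690 genes were called, 51 higher and 117 lower, and the median log2 fold of all genes was -0.481. The count was 571 in set 1 alone, 96 in set 3 alone and 64 with only these groups in the fit. With the animal named in file names as a block it was 29. That fit also held only these groups, with the animal in place of the set term. Its counterpart without the block is therefore 64 and not 168. Among the named genes that still passed with the block were Cish, Cx3cr1, Eomes, Id2, Rgs2, Cxcr6, Rpl13, Rpl23 and Rps18, while Gzmb, Gzma, Itgae, Pdcd1 and Cd44 did not. When each library was left out in turn 31 of the 44 named calls held. Those of Itgae (adjusted p = 0.188), Cd44 (0.197, at a log2 fold of 1.29) and Ifng (0.135) were lost without CD44shi replicate 4, and those of Ccl4 (0.494) and Jund (0.575) without CD44shi replicate 3. The label of replicate 3 is open to doubt, since its Cd44 and Itgae (1.175 CPM on the scale of all 36 libraries) were at or under Tvm levels, although its Gzmb at 50.7, Csf1 at 498.2 and Id2 at 1859 CPM lay above every SP Tvm library. Without it 158 genes were called, 145 of them among the 168. Also lost in some of the leave-one-out fits were Anxa1, Gstm5, Tmevpg1, Airn, Plac8, Egr1, Klrc1 and Klf6. Under at least 1 of the other alternatives 38 of the 44 were lost. In set 3 the CD44shi libraries, replicates 3 and 4, detected 5476 and 5541 genes against 9339 and 9982 in Tvm, and over genes with at least 10 counts in the pair they correlated at Spearman's 0.092 with each other, against 0.938 for replicates 1 and 2. The 2 Tvm libraries of set 3, replicates 4 and 5, correlated at 0.247, and replicate 4, of 2028265 counts, at 0.305 to 0.337 with replicates 1 to 3.

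The changes of both models were compared directly. Of the called genes, 31 rose and 59 fell in both, where 0.257 and 1.33 would be shared by independent lists, and none moved in opposite directions. Both lists came from 1 fit with the same spread for each gene, so chance sharing may be higher than these numbers. Most of the 59 were ribosomal protein genes or copies of them. The ribosomal protein list had an estimated correlation of 0.274, so these genes do not count as independent. With the animal as a block in SP, 26 genes were shared by the file names, 6 up and 20 down, and 23 by the column headers. The SP fit then held only SP CD44shi and SP Tvm, so this fall is not due to the block alone. Of the 208 genes called in AT 186 had the same sign in SP, and of the 168 called in SP 167 had the same sign in AT. Across all tested genes the fold changes correlated at Pearson's r = 0.246, and across the 286 genes called in either at 0.617; these are correlations across genes, which are not independent replicates. No gene passed edgeR's test of the difference between the changes, while 743 had an unadjusted p under 0.05, DESeq2 called 517 and limma-voom 81. Only list tests passed: ribosomal protein genes (camera adjusted p = 6.56e-10), proliferation (1.46e-05), oxidative phosphorylation (1.56e-05), naive and quiescence (0.00164) and tissue egress (0.032) lay higher in the AT change, and the 2 measured gamma-delta and innate genes (0.032) lay higher in the SP change. All were lost at an adjusted p = 0.141 with an estimated correlation. The summed proliferation genes were at 2557 ± 650 CPM in AT CD44shi and 966 ± 184 in AT Tvm, against 1154 ± 332 and 945 ± 206 CPM in SP.

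**Figure D2:**
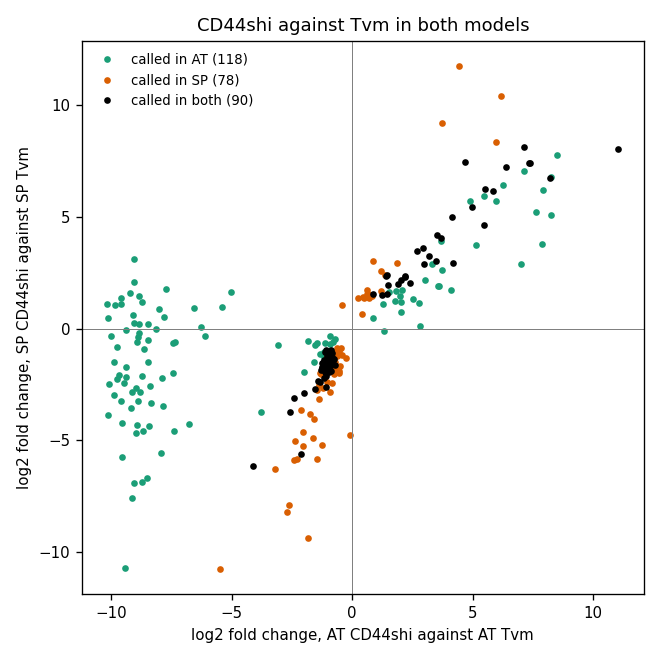
Log2 fold change of CD44shi against Tvm in AT (x axis) and SP (y axis) for each gene called in at least 1 model, coloured by where it was called. The 90 genes called in both share their sign, and genes at 0 counts in AT CD44shi lie at the left.

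In skin of AT mice, CD44shi cells differed from those of the LN in genes of tissue egress, in Icos, Jun and Ccl1, and in transcripts of skin cells. Eomes was at 2.73 ± 5.31 CPM (n = 4) in skin and 79.7 ± 46.3 CPM (n = 5) in LN. Sidt1 fell by 9.44 ± 0.80 and S1pr1 by 4.01 ± 0.92 on the log2 scale. Icos, a costimulatory receptor, rose from 347.2 ± 122.99 to 1513 ± 519 CPM, Jun, an AP-1 factor, from 126 ± 60 to 589 ± 112 CPM, and Ccl1, a T cell chemokine, from 0.461 ± 1.030 to 195 ± 153 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.00854 for Eomes, 3.67e-11 for Sidt1, 0.0358 for S1pr1, 0.00854 for Icos, 7.66e-05 for Jun and 0.0218 for Ccl1.

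Keratinocyte markers stood out among the lists, with 1 of 13 rising (9 adjusted over the list alone; camera adjusted p = 7.34e-19). It was Lgals7, for the epithelial galectin-7, at 81.9 ± 64.7 CPM against 1 count over the 5 LN libraries. The summed keratinocyte markers ranged from 57.6 to 1567 CPM in skin and from 0.747 to 55.3 CPM in LN. Fibroblast and endothelial markers rose in 1 of 10, Dcn, a matrix proteoglycan, at least 2777-fold (6 adjusted over the list alone; camera adjusted p = 6.74e-07), and red cell and platelet markers in 1 of 7, Hba-a1, a haemoglobin chain (4 adjusted over the list alone; camera adjusted p = 7.47e-05). Myeloid markers had none called (7 adjusted over the list alone; camera adjusted p = 7.47e-05, and an adjusted p = 0.08 with an estimated correlation). Stress and immediate-early genes rose in 2 of 20, Jun and Hspa1a, a heat-shock chaperone (14 adjusted over the list alone; camera adjusted p = 3.37e-08), and their summed level was 10491 ± 1141 against 4623 ± 421 CPM. These skin-cell, red-cell and stress signals were found between the same skin and LN libraries as the gene groups that follow.

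Naive and quiescence genes fell in 3 of 20, among them S1pr1 and Txk (7 adjusted over the list alone; camera adjusted p = 1.61e-10), and tissue-egress genes in 2 of 10 (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000914). Cytokines and chemokines rose in 1 of 17 (7 adjusted over the list alone; camera adjusted p = 9.6e-07) and tissue-residency genes in 1 of 16, Rgs2, at 1.12 ± 0.22 (3 adjusted over the list alone; camera adjusted p = 0.000307). T cell receptor-induced genes had 1 of 20 rising, Egr1 (4 adjusted over the list alone; camera adjusted p = 0.00128). No proliferation gene was called, while the list lay lower in skin (camera adjusted p = 1.53e-08), with summed levels of 1324 ± 178 against 2557 ± 650 CPM. These calls held with an estimated correlation. Those of ribosomal proteins (0 of 40; camera adjusted p = 3.18e-07, adjusted p = 0.131 with an estimated correlation) and virtual memory markers (3 of 15 fell, Bcl2, Ly6c2 and Eomes; 0.0144, and an adjusted p = 0.1 with an estimated correlation) were lost. Lost as well were those of the interferon response, which lay lower (0 of 40; 0.00156, and an adjusted p = 0.131 with an estimated correlation), and of glycolysis, which lay higher (0 of 18; 0.0108, and an adjusted p = 0.1 with an estimated correlation). The call of inhibitory and costimulatory receptors was lost too (1 of 15 rose, Icos; 0.0469, and an adjusted p = 0.139 with an estimated correlation).

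The other named calls were rises of Slc5a3, Rrp8, Znf512b and Myg1, and falls of Dpp4 (at least 181-fold), F2rl1 (at least 144-fold) and Treml2. Gzmb at 610 ± 243 against 222 ± 112 CPM and Gzma at 1241 ± 478 against 255 ± 126 CPM did not pass (adjusted p = 0.687 and 0.193). Nor did Ifng at 419 ± 78 against 133 ± 68 CPM or Itgae at 432 ± 129 against 158 ± 106 CPM. Pdcd1 was at 174 ± 30 against 5.51 ± 8.71 CPM, Cd44 at 1093 ± 228 against 497 ± 193 CPM and Klrk1 at 192 ± 38 against 140 ± 43 CPM, and none of the 3 passed. Here too the test used the spread shared by all groups and not these SDs. Also without a call were Prf1 at 26.8 ± 17.1 against 16.9 ± 22.5, Fasl at 44.3 ± 22.6 against 43.5 ± 19.0 and Tbx21 at 175.5 ± 51.9 against 123.5 ± 52.4 CPM. Il2rb was at 755 ± 230 against 497 ± 115 CPM, Il18r1 at 224 ± 73 against 410.5 ± 344.3 CPM and Cxcr3 at 74.1 ± 7.4 against 164 ± 65 CPM. Mki67 was at 62.8 ± 16.2 against 183 ± 60 CPM, Cd8a at 659 ± 179 against 619 ± 244 CPM and Itga4 at 2.74 ± 3.11 against 9.30 ± 9.01 CPM, and none of these 6 passed. Il12rb2 had 11 counts in 1 of 4 skin libraries and 0 in LN.

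In all, 37 of 12690 genes were called, 25 higher and 12 lower in skin, against 1889 at an unadjusted p under 0.05. The count was 11 without skin replicate 4, 17 without skin replicate 1, 19 without LN replicate 1, 63 without LN replicate 2, 336 without set 3, 160 in set 2 alone and 28 without the 2 skin libraries of most keratinocyte signal. Of the 22 named calls 5 held when each library was left out in turn, those of Sidt1, Eomes, Jun, Dcn and Rrp8, and 18 were lost under at least 1 of the other alternatives. The single SP skin library had no replicate. Its direction against the 2 SP LN CD44shi libraries of the same set, 1 of them replicate 3, was scored as that of the AT model for 28 of the 37 genes. Lgals7, Dpp4 and Treml2 were at 0 CPM on both sides and hold no direction, but were scored too. The 28 is therefore too high as a count of agreement, and the share over all genes was not counted. In the SP skin library Icos was at 960 CPM, Jun at 1102 CPM and Ccl1 at 247.5 CPM, and the summed keratinocyte markers were at 2.76 CPM. Among the genes that went the other way were Sidt1 (25.04 against 0.785 CPM in those LN libraries) and Dcn (0 against 21.53 CPM).

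**Figure D3:**
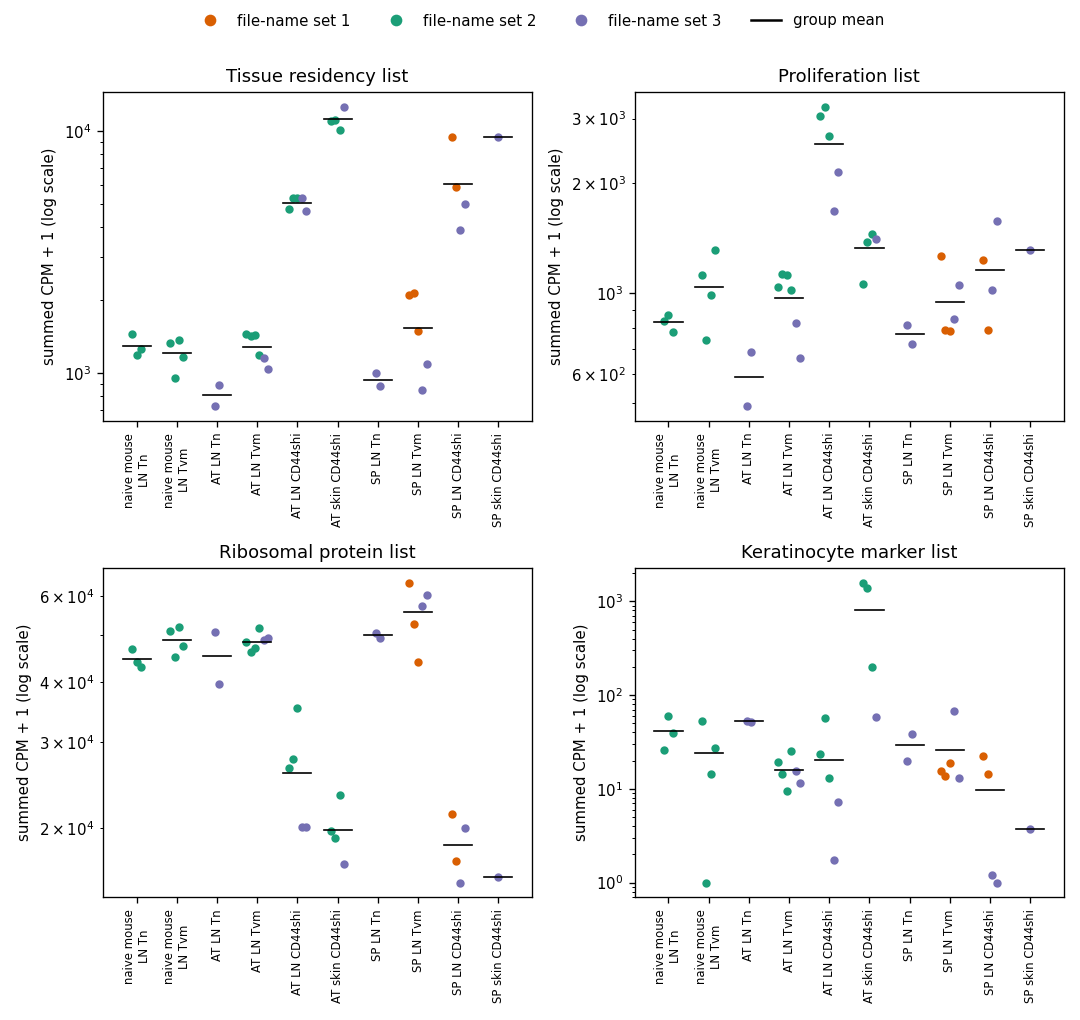
Summed CPM + 1 on a log scale (y axis) of tissue-residency, proliferation, ribosomal protein and keratinocyte marker genes in each library by group (x axis), with points coloured by file-name set and a bar at the group mean. Residency genes averaged 11193 CPM in AT skin CD44shi, 5056 CPM in AT LN CD44shi and 1276 CPM in AT LN Tvm.

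Tvm cells of naive mice differed from Tn cells in the markers by which virtual memory cells are known. Of 15 virtual memory markers 5 rose and none fell (12 rose adjusted over the list alone; camera adjusted p = 7.06e-40, held with an estimated correlation), and their summed level was 3886 ± 868 CPM (n = 4) against 780 ± 44 CPM (n = 3). Ccl5, a chemokine stored by memory T cells, was at 1014 ± 485 against 6.87 ± 5.00 CPM, Il2rb, the chain shared by the IL-2 and IL-15 receptors, at 496 ± 101 against 58.5 ± 11.01 CPM, and Xcl1 at 59.5 ± 14.2 against 1.88 ± 1.51 CPM. Gzmm, for granzyme M, rose at 6.12 ± 1.32 and Cd44 (chromosome 2, 102811141 to 102901665) at 6.94 ± 0.67 on the log2 scale. The adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 2.62e-11 for Ccl5, 1.02e-07 for Il2rb, 0.00035 for Xcl1, 0.0289 for Gzmm and 2.95e-09 for Cd44.

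Of 17 cytokine and chemokine genes 3 rose, Ccl5, Xcl1 and Ccl4 (5 adjusted over the list alone; camera adjusted p = 1.13e-06), and of 21 NK receptors 2, Slamf7 and Klrc1 (2 adjusted over the list alone; camera adjusted p = 0.00161). Of 18 cytokine receptor genes 1 rose, Il2rb (4 adjusted over the list alone; camera adjusted p = 8.94e-05), and of 15 cytotoxic effectors 1, Gzmm (1 adjusted over the list alone; camera adjusted p = 8.94e-05). Of 22 effector and memory transcription factors none was called (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00433). These calls held with an estimated correlation. Chemokine receptors rose in 2 of 15, among them Ccr10 (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00207), a call lost at an adjusted p = 0.0523 with an estimated correlation. Also lost were the calls of adhesion genes (1 of 17 rose; 0.0155, and an adjusted p = 0.0984 with an estimated correlation) and proliferation genes (0 of 38; 0.00653, and an adjusted p = 0.305 with an estimated correlation). The same held for ribosomal proteins (0 of 40; 0.0155, and an adjusted p = 0.5 with an estimated correlation) and the 2 gamma-delta and innate genes (0.0272, and an adjusted p = 0.118 with an estimated correlation). The latter summed to 13.6 ± 9.1 against 0.0398 ± 0.0689 CPM. Plek rose at 8.43 ± 1.59. Cxcr3 at 47.6 ± 23.2 against 3.61 ± 2.62 CPM (adjusted p = 0.0842), Eomes at 222 ± 64 against 43.0 ± 5.0 CPM and Tbx21 at 42.9 ± 28.0 against 5.79 ± 2.92 CPM (adjusted p = 0.947 and 0.126) did not pass. Itga4, for the integrin CD49d by whose low level virtual memory cells are often told apart, was at 15.5 ± 11.3 against 102 ± 5 CPM and did not pass. The p-values of Eomes and Itga4 used the spread shared by all groups and not these SDs, so equal levels are not shown. Gzmb was at 0.117 ± 0.233 against 0.185 ± 0.209 CPM, Gzma at 0.543 ± 0.788 against 1.03 ± 0.92 and Prf1 at 7.34 ± 4.17 against 4.98 ± 1.52 CPM. Ifng was at 3.35 ± 4.07 against 0.359 ± 0.166, Fasl at 6.99 ± 4.79 against 2.78 ± 4.50 and Klrk1 at 12.7 ± 7.5 against 2.84 ± 2.23 CPM. Il18r1 was at 109 ± 38 against 40.8 ± 26.9 CPM and Ly6c2 at 782 ± 269 against 220.2 ± 39.4 CPM. Itgae was at 7.14 ± 7.56 against 27.8 ± 5.3, Mki67 at 19.4 ± 14.3 against 3.98 ± 3.21 and Cd8a at 234 ± 64 against 322 ± 58 CPM. Il12rb2 and Pdcd1 were at or under 2.23 CPM in both groups, and none of these genes passed.

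In all, 14 genes were called and all rose; 28 were called with only these groups in the fit, 52 without set 3 and 40 without the low-count filter. Of the 10 named calls 7 held in every leave-one-out fit, and those of Plek, Gzmm and Ccr10 did not; 7 were lost under at least 1 of the other alternatives. The same comparison within AT mice called 85 genes (80 higher and 5 lower) and within SP mice 28 (21 higher and 7 lower), each against 2 Tn libraries. All 14 genes were also called higher in AT, where 0.088 would be shared by independent lists, and 13 in SP, where 0.023 would be. The lists came from 1 fit with the same spread for each gene, so they are not independent and chance sharing may be higher. Xcl1, Gzmm, Plek, Ccl5, Ccl4, Ccr10, Il2rb, Cd44 and Klrc1 were among the 13 called in all 3. Virtual memory markers rose in 7 of 15 in AT (11 adjusted over the list alone; camera adjusted p = 4.9e-19) and 6 of 15 in SP (10 adjusted over the list alone; camera adjusted p = 2.16e-25), and both held with an estimated correlation. In AT, Tn libraries detected fewer genes, 7858 ± 375 against 10416 ± 880, correlated at Spearman's 0.262 with each other, and 40 of the 85 called genes were at 0 in 1 of the groups. Keratinocyte, fibroblast and red cell markers lay lower in AT Tvm than in Tn (camera adjusted p = 0.00213, 0.00432 and 0.00514), calls lost at an adjusted p = 0.269, 0.142 and 0.164 with an estimated correlation.

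In AT, Slamf7, Cd44, Klrc1 and Pogk had no counts in Tn and were at least 341.5-fold, 418-fold, 400-fold and 230.1-fold higher in Tvm. The 5 genes called lower in Tvm were Hspb1, Alms1 and, chosen after their values were seen, Hba-a1, Slc15a3 and Adtrp. Of the Tn counts 352 of 363 for Hspb1 and 820 of 820 for Alms1 lay in Tn replicate 1. In SP, Gzmm, Ctla2a and Cd44 had no counts in Tn and were at least 1449-fold, 1630-fold and 452-fold higher in Tvm, and Ccl5 was at 1562 ± 797 CPM against 3 counts. Nsun6, Rrp8, Nr4a3 and Zfp212 were called lower in SP Tvm; in set 3, the only set with both groups, the 2 SP Tvm libraries held no counts of the first 3 and 0 and 18 counts of Zfp212. Nr4a3 was at 12.4 ± 14.4 CPM over all 5 SP Tvm libraries and 7.48 ± 10.58 CPM in Tn, so its direction rests on set 3. The AT count was 37 without Tn replicate 1, 288 without Tn replicate 2, 12 in set 3 alone and 448 with only these groups, and the ribosomal protein median of 0.036 in AT turned to -0.304 under DESeq2's size factors. The SP count was 13 without Tn replicate 2, 210 without Tvm replicate 5, 11 in set 3 alone and 15 with only these groups.

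Tvm cells of AT mice were compared with those of naive mice to ask whether the disease changed them. No gene passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, while 511 had an unadjusted p under 0.05, DESeq2 called 292 and limma-voom 1. Granzyme transcripts were low in both: Gzmb at 1.78 ± 2.54 CPM (n = 6) in AT Tvm and 0.117 ± 0.233 CPM (n = 4) in naive-mouse Tvm, and Gzma at 5.71 ± 5.38 against 0.543 ± 0.788 CPM. Of the 21 NK receptors none was called, but the list lay higher in AT (19 of 21 with a positive fold; camera adjusted p = 0.000448, held with an estimated correlation). Klrk1 of that list was at 32.6 ± 16.8 against 12.7 ± 7.5 CPM. AT Tvm libraries also detected more genes, 10416 ± 880 against 8995 ± 1454, and the median log2 fold of all tested genes was 0.171. The other 25 lists passed no camera test. The focus genes with the next largest folds were Ifng at 22.7 ± 18.6 against 3.35 ± 4.07, Fasl at 31.1 ± 11.4 against 6.99 ± 4.79, Pdcd1 at 21 counts against 2 (a ratio of 1.35 to 48.5 by its 95% counting interval), and Il12rb2 at 4.62 ± 3.43 against 1.98 ± 3.11 CPM. Cd44, Cxcr3, Itgae, Cd8a, Il2rb, Eomes, Tbx21, Prf1, Il18r1, Ly6c2, Itga4 and Mki67 had fitted log2 folds between -0.94 and 1.03. The count was 11 without the low-count filter and 1 in set 2 alone, without Tvm replicate 4 or without Tvm replicate 6 of AT.

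Tvm cells of SP mice and naive mice shared no file-name set, so that this contrast depended on the set term. By edgeR 2 genes passed. Fgl2, for a fibrinogen-like protein secreted by T cells, was at 28.3 ± 12.4 CPM (n = 5) against 0.202 ± 0.195 CPM (n = 4), with an adjusted p = 0.0146. Nr4a3, a nuclear receptor induced by T cell receptor signals, was at 12.4 ± 14.4 against 48.7 ± 6.4 CPM (adjusted p = 0.0464). No gene was called with only these groups, where the set was fully confounded, or without naive-mouse Tvm replicate 2. The count was 1 without SP Tvm replicate 2 or 3 or naive-mouse Tvm replicate 3, 4 without naive-mouse Tvm replicate 4, 28 without the low-count filter and 110 without SP Tvm replicate 5.

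Tn cells were compared with naive-mouse Tn cells in the same way, with 2 libraries in each model and no shared set. In AT 21 genes passed, 2 higher and 19 lower. Hspb1, a small heat-shock protein, was at least 225-fold higher than in naive mice, and 352 of its 363 counts lay in Tn replicate 1. The other was the haemoglobin gene Hba-a1 at a log2 fold of 6.90, chosen after its value was seen; Tn replicate 1 held 946 of its counts and replicate 2 held 5, and the summed red cell markers were at 244 and 1.12 CPM. Keratinocyte and fibroblast markers lay higher in AT Tn with no gene called (camera adjusted p = 0.0434 for each, and an adjusted p = 0.733 with an estimated correlation). Klf7, Mapkap1, Mcm3, a subunit of the replicative helicase, and Me2 had no counts in AT Tn and were at least 205-fold, 167-fold, 199.5-fold and 145.5-fold lower. These bounds do not cover the lower number of genes detected in AT Tn, 7858 ± 375 against 10101 ± 424 in naive-mouse Tn. The count was 177 without AT Tn replicate 2, 5 without AT Tn replicate 1 and 0 with only these groups. In SP 3 genes passed, all lower. Ctla2a fell at least 53.65-fold (adjusted p = 6.14e-05), and the others, chosen after their values were seen, were Ccl5 and Tbx21, with adjusted p = 0.00638 and 0.00877. The count was 0 without SP Tn replicate 1, 1 without SP Tn replicate 2 and 0 with only these groups.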

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

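The tests of library complexity, of the summed marker genes in skin and of the stress genes were chosen after the result each concerns was seen; the tests of scaling, short transcripts, genes called higher outside the marker lists and other splits of the libraries were not.

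Ribosomal protein genes were lower in CD44shi than in Tvm cells of both models, and their list differed between the models by camera at a preset correlation (adjusted p = 6.56e-10) but not with an estimated correlation (adjusted p = 0.141), with 18434 ± 2688 CPM in SP and 25957 ± 6294 CPM in AT CD44shi. A scaling error shared by abundant genes was argued against: the ribosomal median lay -0.838 (AT) and -1.86 (SP) from that of the other genes of at least 500 CPM. Loss of short transcripts was argued against by medians of -0.906 (AT) and -1.557 (SP) relative to genes with transcripts as short. Fewer detected genes as the whole source was argued against in SP, where gene numbers overlapped in set 1 and the least different pair of libraries still differed by -1.044. In AT gene numbers did not overlap between CD44shi and Tvm, so that comparison cannot tell complexity and cell state apart (-0.699 in set 2). Other libraries with few genes argue against complexity as the whole source there. Naive-mouse Tvm replicates 1 to 3, with 8836, 7593 and 8524 genes, held at least 44926 CPM of ribosomal protein genes. AT Tn, with 8123 and 7593 genes, held at least 39561 CPM. The AT CD44shi libraries, with 5986 to 8941 genes, held 20076 to 35227 CPM. A lower ribosomal share in CD44shi cells may be a property of the cells in SP, as a hypothesis found and tested on the same data.

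In skin, 3 of 4 lists of other cells' markers (keratinocyte, fibroblast, red cell) lay above every AT LN CD44shi library in at least 3 of the 4 AT skin libraries, and RNA of other cells, for the marker genes, may be their source. Lgals7 was at 81.9 ± 64.7, Dcn at 168 ± 182 and Hba-a1 at 873 ± 684 CPM in skin. CD44shi is read here as very high CD44 with gates not given, so which other cells the sort would leave out is not known. For the 22 genes called higher outside the marker lists RNA that follows the keratinocyte signal was argued against, while RNA of cells spread otherwise over the libraries was not tested and genes that vary between skin libraries are less often called: between the 2 skin libraries with most and the 2 with least keratinocyte signal their median differed by -0.086 (quartiles -0.566 to 0.379), while the keratinocyte sum differed by 3.521. The 14 stress genes that rose, adjusted over the list alone, leave open whether release of cells from skin or the tissue itself changed them, since every skin library shares both. Red cell markers stood at 16.37 CPM in AT skin replicate 4 against 994.5 to 2123 CPM in the others, and proliferation genes at 1060 CPM in replicate 1 against 1382 to 1452 CPM.

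By camera at a preset correlation the AT and SP changes from Tvm to CD44shi differed in 5 more lists: proliferation (adjusted p = 1.46e-05), oxidative phosphorylation (1.56e-05), naive and quiescence (0.00164), tissue egress (0.032) and the 2 gamma-delta and innate genes (0.032). With an estimated correlation all were lost, at an adjusted p = 0.141. No gene passed that test in edgeR against 743 at an unadjusted p under 0.05. Any split reaches a real count of 0, as 60 of 60 did (highest other 21), so the splits say nothing about chance here.

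Other splits of the same libraries were counted with only the compared groups in the fit. The real split called more genes than any other for CD44shi against Tvm in AT (249 genes, highest other 2, 1 of 100 splits as large) and in SP (64, highest other 0, 1 of 100). It also did for skin against LN (49, highest other 23, 1 of 100) and for Tvm against Tn in naive mice (28, highest other 0, 1 of 35). Each share counts the real split itself and could not be lower, so chance is not excluded. The splits also ignored the animals named in some file names, and with that block SP had 29 genes. The splits say nothing about chance for AT against naive-mouse Tvm (0, highest other 45; 100 of 100) or SP against naive-mouse Tvm (0, highest other 940; 100 of 100), since any split reaches a real count of 0. The split of 45 put naive-mouse replicates 3 and 4 with the 4 set 2 AT libraries, and set 2 alone gave 1 gene for the real groups. The split of 940 put SP Tvm replicate 4 or 5, both of set 3, with all naive-mouse libraries against the rest, and no set holds both real groups. With the set term both these splits rest on replicate 4 against replicate 5, the only libraries of 1 set on opposite sides, so they show that these 2 libraries differ.

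Single libraries far from the rest of their group by Dixon's test came in 2 of 18 groups of library measures, 19 of 114 groups of gene levels and 9 of 54 groups of summed lists. Chance gives about 1 in 20 groups only for normally distributed values. A lone trace value among zeros is always flagged, as for Gzmb, Il12rb2 and Pdcd1 below. The numbers flagged therefore do not measure an excess over chance. These CPM were scaled over all 36 libraries. Total counts, in units of 1e+06, were 11.94 in SP LN CD44shi replicate 4 against 7.154 to 7.656, and Rn45s took 57.02% of AT LN Tvm replicate 6 against 34.4% to 41.2%.

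Among SP LN CD44shi libraries, Itgae was at 1.175 CPM in replicate 3 against 251.1 to 469.8 CPM and Cd8a at 1284 CPM in replicate 4 against 663.5 to 697.2 CPM. In AT LN CD44shi, Il2rb was at 707.5 CPM in replicate 5 against 429.2 to 458.7 CPM. Myeloid markers summed to 955.8 CPM in replicate 3 against 281.4 to 400.2 CPM, and fibroblast markers to 0.7191 CPM in replicate 5 against 36.75 to 64.5 CPM. In AT skin, replicate 3 had Eomes at 10.65 CPM against at most 0.2139 CPM, Gzma at 1946 CPM against 953.7 to 1077 CPM and Il12rb2 at 1.22 CPM against 0.

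In SP LN Tvm, replicate 4 had Cd44 at 47.02 CPM against 82.55 to 93.9 CPM, Eomes at 648.8 CPM against 314.9 to 361.1 CPM and Prf1 at 0 against 6.508 to 15.59 CPM. It also had more B cell (288.2 against 30.13 to 54.64 CPM), fibroblast (109.9 against 10.23 to 17.77 CPM) and keratinocyte markers (66.64 against 11.88 to 18.02 CPM). Replicate 5 had Il2rb at 1293 CPM against 461.8 to 591.8 CPM, Cxcr3 at 226.9 CPM against 91.68 to 96 CPM, myeloid markers at 162.7 CPM against 226.5 to 247.3 CPM and red cell markers at 0.1033 CPM against 20.85 to 43.16 CPM. Pdcd1 was at 0.1317 CPM in replicate 1 and 0 in the others.

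In AT LN Tvm, replicate 4 had Fasl at 10.51 CPM against 26.13 to 41.12 CPM and Ly6c2 at 634.4 CPM against 1110 to 1162 CPM. In naive-mouse Tvm, replicate 2 had Cd8a at 135.3 CPM against 250.9 to 276.2 CPM, Fasl at 0 against 7.64 to 10.03 CPM and Mki67 at 0.3394 CPM against 19.27 to 34.19 CPM. Replicate 3 had Eomes at 311.5 CPM against 181.8 to 188.4 CPM and Gzmb at 0.4558 CPM against 0. No biological explanation of these single values was tested.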

How the results depend on the processing

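The alternatives without Rn45s, without file-name set 3, with limma-voom, with animals named by the column headers and without the 2 skin libraries of most keratinocyte signal were chosen after the data were examined; the others were fixed before. Among named genes that were called, 1132 of the values under alternatives other than leaving out 1 library kept direction and call and 321 lost the call, and when 1 library was left out 949 kept both and 276 lost the call. No called named gene reversed. Where a value below changed, the cause was not tested, except that fewer libraries or more genes are part of some alternatives' own construction.

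Gene counts in the order of the comparisons in the methods ran as follows. DESeq2's Wald test called 1214 (CD44shi against Tvm in AT), 841 (in SP), 1029 (AT skin against LN), 292 (AT against naive-mouse Tvm), 419 (naive-mouse Tvm against Tn), 696 (SP against naive-mouse Tvm), 1937 (AT Tvm against Tn), 924 (SP Tvm against Tn), 517 (the difference between AT and SP), 1554 (AT against naive-mouse Tn) and 486 (SP against naive-mouse Tn). No low-count filter gave 97 for skin, 11 for AT against naive-mouse Tvm, 40 for naive-mouse Tvm against Tn, 28 for SP against naive-mouse Tvm, 187 and 54 for AT and SP Tvm against Tn, 25 for the difference between models, and 59 and 11 for AT and SP against naive-mouse Tn. With limma-voom the counts were 510 and 1712 for CD44shi in AT and SP, 215 for skin, 1 for AT against naive-mouse Tvm, 25 for AT Tvm against Tn, 81 for the difference, and 3 and 0 for AT and SP against naive-mouse Tn. DESeq2's size factors gave 1 for SP against naive-mouse Tvm.

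Without the set term 21 genes were called in skin, 1 for the difference and 35 for AT against naive-mouse Tn. With replicate numbers as a block, a pairing the labels do not state, the counts were 110 for CD44shi in AT, 1 for AT and 1 for SP against naive-mouse Tvm, 23 for AT Tvm against Tn and 3 for AT against naive-mouse Tn. With the animal as a block and only the compared groups in the fit, CD44shi in SP had 29 genes by file names and 25 by column headers. Those groups without the animal block gave 64. Without set 3 there were 348 for CD44shi in AT, 336 for skin, 1 and 18 for AT and SP against naive-mouse Tvm and 52 for naive-mouse Tvm against Tn. With only the compared groups there were 64 for CD44shi in SP, 28 for naive-mouse Tvm against Tn, 0 for SP against naive-mouse Tvm, 448 and 15 for AT and SP Tvm against Tn, and 0 and 0 for AT and SP against naive-mouse Tn. Set 1 alone gave 571 for CD44shi in SP. Set 2 alone gave 160 for skin and 1 for AT against naive-mouse Tvm. Set 3 alone gave 12 and 96 for CD44shi in AT and SP, and 12 and 11 for AT and SP Tvm against Tn.

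The 90 genes shared by both CD44shi comparisons became 136 without the filter, 275 with DESeq2, 218 with limma-voom and 10 in set 3 alone. With the animal as a block in SP, and only the compared groups in that SP fit, they became 26 by the file names and 23 by the column headers. All of these were among the 90.

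Leaving out 1 library at a time, counts ranged from 110 to 202 for CD44shi in AT, 11 to 63 for skin, 0 to 1 for AT against naive-mouse Tvm, 0 to 110 for SP against naive-mouse Tvm, 37 to 288 and 13 to 210 for AT and SP Tvm against Tn, 0 to 2 for the difference, and 5 to 177 and 0 to 3 for AT and SP against naive-mouse Tn. The ends came without AT LN CD44shi replicate 4 (110), AT skin replicate 4 (11), AT LN CD44shi replicate 2 (63), SP LN Tvm replicate 5 (110 and 210), SP LN Tn replicate 2 (13), and AT LN Tn replicates 1 (37 and 5) and 2 (288 and 177). Depth limited the folds of 40 called genes of CD44shi in AT and 4 in SP, which had no counts in 1 group. Where a single Tn library was left it was assumed to vary like the other groups.

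Of the list results under other alternatives, 324 kept direction and call, 79 lost the call, 11 gained it and 2 reversed: by the fry rotation test the interferon response (adjusted p = 0.776) and oxidative phosphorylation (0.845) of CD44shi in AT pointed the other way.

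Among named genes that were not called, 700 values under alternatives other than leaving out 1 library kept direction and side, 51 gained a call and 25 reversed. Of the 51, 12 came with limma-voom, 10 without the low-count filter, 10 with only the compared groups and 8 with DESeq2's Wald test. A further 5 came without set 3, 5 in set 1 alone and 1 in set 2 alone, and these genes are not named here. Leaving out 1 library, 657 kept both and 27 reversed. Those that reversed are given as log2 folds. For CD44shi in AT, Itga4 was -0.82 with limma-voom and -0.48 to 1.40 leaving out 1 library, and Prf1 -1.29 to 0.0847. In SP, Itga4 was 0.72 without set 3, 0.21 with limma-voom, 0.73 in set 1 alone and -2.90 to 0.32 leaving out 1 library, and Prf1 was -0.16, -0.0686 and -0.15 in the first 3. In skin, Tbx21 was -0.0082 and Fasl -0.13 without set 3, Fasl -0.10 in set 2 alone and -0.24 to 0.26 leaving out 1 library, Itga4 0.34 with limma-voom, and Il12rb2 -0.0392 to 4.60.

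For AT against naive-mouse Tvm, Cd44 was 0.17 and Cxcr3 0.27 without the set term, Cd44 0.017 and Cxcr3 0.0144 without Rn45s, and Cd44 0.026 and Itgae -0.0701 without set 3. With limma-voom Cd44 was 0.0793, Cxcr3 0.18 and Pdcd1 -0.16. With only these groups Cd44 was 0.0164 and Itgae -0.0792, and in set 2 alone Cd44 was 0.0062 and Itgae -0.085. Leaving out 1 library, Cd8a was -0.0263 to 0.26, Cd44 -0.19 to 0.22, Cxcr3 -0.24 to 0.33, Pdcd1 -0.40 to 2.30 and Itgae -0.30 to 1.00. For naive-mouse Tvm against Tn, Pdcd1 was 0.0478 with limma-voom and -0.96 to 2.44 leaving out 1 library, Gzmb -3.70 to 0.58, Gzma -2.76 to 0.0155 and Il12rb2 -2.21 to 0.79.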

Other observations

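No test in this part was chosen after its result was seen, since it reports values only.

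The single SP skin CD44shi library, which entered no test, carried the granzymes at 759 CPM for Gzmb and 867 CPM for Gzma, against 611 ± 240 and 1244 ± 471 CPM in AT skin on the scale of all 36 libraries. Prf1 was at 126 CPM, against 40.2 CPM on average in the 2 SP LN CD44shi libraries of its set and 26.7 ± 17.0 CPM in AT skin. Fasl was at 173 CPM against 33.9 CPM in those LN libraries and 44.4 ± 22.4 CPM in AT skin. Pdcd1 was at 165 CPM and Cd44 at 1518 CPM. Klrk1 was at 17.5 CPM, against 243 CPM in the LN libraries and 192 ± 37 CPM in AT skin. Ly6c2, S1pr1 and Eomes had no counts. Hspa1a was at 149 CPM against 0, and Cd8a at 1520 CPM against 983 CPM. With 1 library and 4900 detected genes, no spread between animals can be given.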
